A study of Mus musculus with 3 samples.

How the data were processed

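Expression was measured in 3 samples of sorted cap mesenchyme cells from E15.5 mouse kidneys, on one array per sample. Per the labels, the kidneys were treated with trypsin for 5 minutes at 37 °C, the suspension was passed through a mesh of 70 micron, cells were sorted by fluorescence, and total RNA was amplified in 2 rounds and labelled with biotin. Each sample was a pool of about 5 to 10 kidneys, and the sex of the embryos was recorded as unknown. The samples formed a single group with replicate numbers 1 to 3 taken from their titles, and they are called pools 1 to 3.

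The deposited values are linear array intensity signals, 1 per probe set and array, for 45101 probe sets of a mouse Affymetrix array. Per the submitters' processing notes, the authors made them with GCOS, the array software of Affymetrix, whose version and settings the notes do not give. As tested on the values, the mean signal after leaving out the lowest and highest 2% was 1500 on every array, so each array had been scaled to that target. Median signals were 222, 197 and 184 in pools 1, 2 and 3, and the highest signals were 75402, 139283 and 75242. Scaling to a common mean removes differences in total signal between arrays, and the signals do not allow the level of one gene to be ranked against that of another, because probe sets differ in affinity.

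Probe sets were named from the platform annotation. A single gene symbol was given for 34945 probe sets, several for 932 and none for 9160, and 64 were controls. Of the single-gene probe sets, 34741 matched a RefSeq gene by Entrez identifier, and 0 symbols needed an update. The 18193 genes with a single-gene probe set were analysed. Probe sets with several symbols named no gene, and controls were left out of all tests. The genome build behind the probe sets was not named, so no coordinates are given. Members of the gene lists without a single-gene probe set were not analysed here, which left 358 of 391 distinct genes.

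Choices made before the data were examined were the background genes, 25 gene lists, the tests, the rule for named genes and the alternatives, apart from those said to be chosen later. Background was represented by 150 probe sets for genes of sensory, hair and mucosal cells, namely 44 olfactory, 36 vomeronasal and 3 bitter taste receptor, 43 keratin-associated protein and 24 defensin probe sets. From log2(signal + 16) of each probe set, the 95th percentile of the background probe sets on the same array was subtracted. The mean over the 3 arrays was tested against 0, one-sided, with limma 3.58.1 in R 4.3.3 (an intercept-only model with eBayes and an intensity trend), and Benjamini-Hochberg adjusted p-values under 0.05 were called above background. The pseudocount of 16 understates differences of weak signals. A gene was above background if any of its single-gene probe sets was, and the probe set with the highest mean log2 signal represented the gene in all values given. A low signal does not show that a transcript is absent, since the call depends on the affinity of the probe set.

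The lists covered cap mesenchyme, early nephron, podocyte, proximal tubule, loop and distal tubule, ureteric bud, stroma, endothelium, macrophage, erythroid, neural, adrenal cortex, lineages of other organs, epithelial genes, proliferation, dissociation stress, 4 signalling systems (FGF and receptor tyrosine kinases, WNT, BMP and TGF-beta, Notch), Hox genes, the sine oculis homeobox, Eya and Dach families, transgene-related loci, sex-linked genes and housekeeping genes. The share of members above background was compared with that of all other named genes, background genes excluded, by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 25 lists. Genes are not independent replicates, so these tests describe the arrays at hand. Pools were compared without a test. For each list with at least 3 genes above background, the median deviation of its genes from their 3-pool mean was taken in each pool, and the range of the medians was placed among 10000 random lists of the same size matched on mean log2 signal in 10 bins. Probe sets whose highest and lowest pools differed by at least 2-fold were counted, and log2 ratios of 3' to 5' control probe sets were computed for each array. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.

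All members of the cap mesenchyme, Hox, sine oculis, Eya and Dach, transgene-related and sex-linked lists could be named. From every other list, up to 3 members with the largest and 2 with the smallest moderated statistic against background could be named, and outside the lists the 10 genes above background with the largest log2 range between pools. Any other gene named is said to be chosen after its values were seen.

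The tests were tested on simulated data first. In a simulation of all 45037 probe sets without controls, 25.5% of 200 probe sets placed 0.5 log2 units over the threshold were called above background, 89% of those at 1 unit and 100% of those at 2 units, while 0.0410% of 21977 probe sets at or below the threshold were called. The latter kept their measured means at any distance below the threshold, so this is not the rate of false calls at the threshold itself. In a simulation of the pool comparison on 9892 genes, 2.5% of 40 random lists exceeded the 95th percentile. A list of 15 genes shifted by 0.6 log2 units in 1 pool lay at the 100th percentile. Smaller shifts were not simulated, and the random lists were drawn gene by gene, without genes that vary together.

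The alternatives were the 99th percentile of background, olfactory and vomeronasal receptors as the only background (80 probe sets), quantile normalization, a pseudocount of 1, leaving out probe sets whose names end in _x_at, _s_at or _a_at and which can match several transcripts, eBayes without the intensity trend, the representative probe set alone, no filter on weak signals in the pool comparisons, and leaving out each pool in turn. The mean over a gene's probe sets in the pool comparison and 5 further gene lists (chromatin repressors, Wnt ligands, imprinted genes, Sox genes, and fetal and self-renewal genes) were added after the data were seen. No comparison between groups was made, since all samples share one group.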

Results

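Gene expression was measured in cap mesenchyme, the progenitor population that surrounds the ureteric tips of the embryonic kidney and gives rise to nephrons. The cells were isolated by fluorescence-activated cell sorting from dissociated kidneys of E15.5 CD-1 mouse embryos (Theiler stage 23) carrying a Six2 transgene that encodes EGFP and cre. The data comprised 3 arrays, each from a pool of about 5 to 10 kidneys, and all 3 belonged to a single group. The question was which transcripts this compartment holds. Without a control group or a second cell population, each gene was compared with the background level of the arrays, and the 3 pools were compared with each other. The number of arrays limits the precision of every value. The p-values of limma measure the spread between these 3 pools, since the labels do not say whether they came from separate litters. Those of Fisher's exact test compare counts of genes and hold no spread between pools. Signals below are linear array intensities with the SD over the 3 pools.

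Transcripts of 9892 of 18193 named genes (54.4%) were above background in the sorted cells. This corresponded to 18699 of 45037 probe sets (41.5%) in limma's one-sided test with Benjamini-Hochberg adjustment. Of the 150 background probe sets, which represent sensory receptor, hair and mucosal defence genes, 2 passed the same test. The threshold was set from these same probe sets, so this is not an independent check. The background level lay at a signal of 197 in pool 1, 186 in pool 2 and 201 in pool 3. Among probe sets above background the median SD between pools was 0.26 on the log2 scale and the median coefficient of variation was 17.9%. Across probe sets above background, which are not independent replicates, Pearson's r was 0.966 for pools 1 and 2, 0.940 for pools 1 and 3 and 0.968 for pools 2 and 3. Of the 6484 genes above background with several probe sets, 4173 had probe sets on both sides of the threshold. For every one of the 25 gene lists, the number of members above background was identical when p-values were adjusted over the list alone.

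Genes of the cap mesenchyme were almost completely represented. Of the 18 measured members of the cap mesenchyme list, 17 were above background, against 54.7% of the other named genes (adjusted p = 0.00173, Fisher's exact test with Benjamini-Hochberg adjustment over 25 lists; odds ratio 14.1, 95% confidence interval 2.20 to 586). Six2, the transcription factor that maintains nephron progenitors, had a signal of 7905 ± 1904 (n = 3), and Cited1, a marker of the uncommitted progenitors, had a signal of 878 ± 121 (n = 3). Eya1, a coactivator that acts with sine oculis homeobox proteins such as Six2, was at 33774 ± 4443, Sall1 at 20670.2 ± 1825, and Gdnf, the ligand that draws out the ureteric bud, at 8235 ± 982 (n = 3 each). Crym (23823 ± 2366), Itga8 (22805 ± 4449.6), Wt1 (10428 ± 3754), Bmp7 (12140.1 ± 855), Ncam1 (17004 ± 3130.2) and Meox1 (1665 ± 232) were also above background in all 3 pools. Spock2, Phf19, Robo2, Traf1, Osr1 and Dpf3 passed the test with adjusted p (limma) of 7.3e-07, 6.5e-06, 0.00013, 0.0015, 0.0024 and 0.016. Osr1, which marks early nephrogenic mesoderm, read 1122, 515 and 356 in pools 1, 2 and 3. Tmem100 was the member that did not pass, with signals of 258, 116 and 186. Dpf3 lost its call when pool 2 was left out and lay under the background level at its 99th percentile, where Osr1 and Traf1 also lost theirs. Some members of this list became known from profiles of such sorted cells, so the list is not fully independent of data of this kind.

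**Figure D1:**
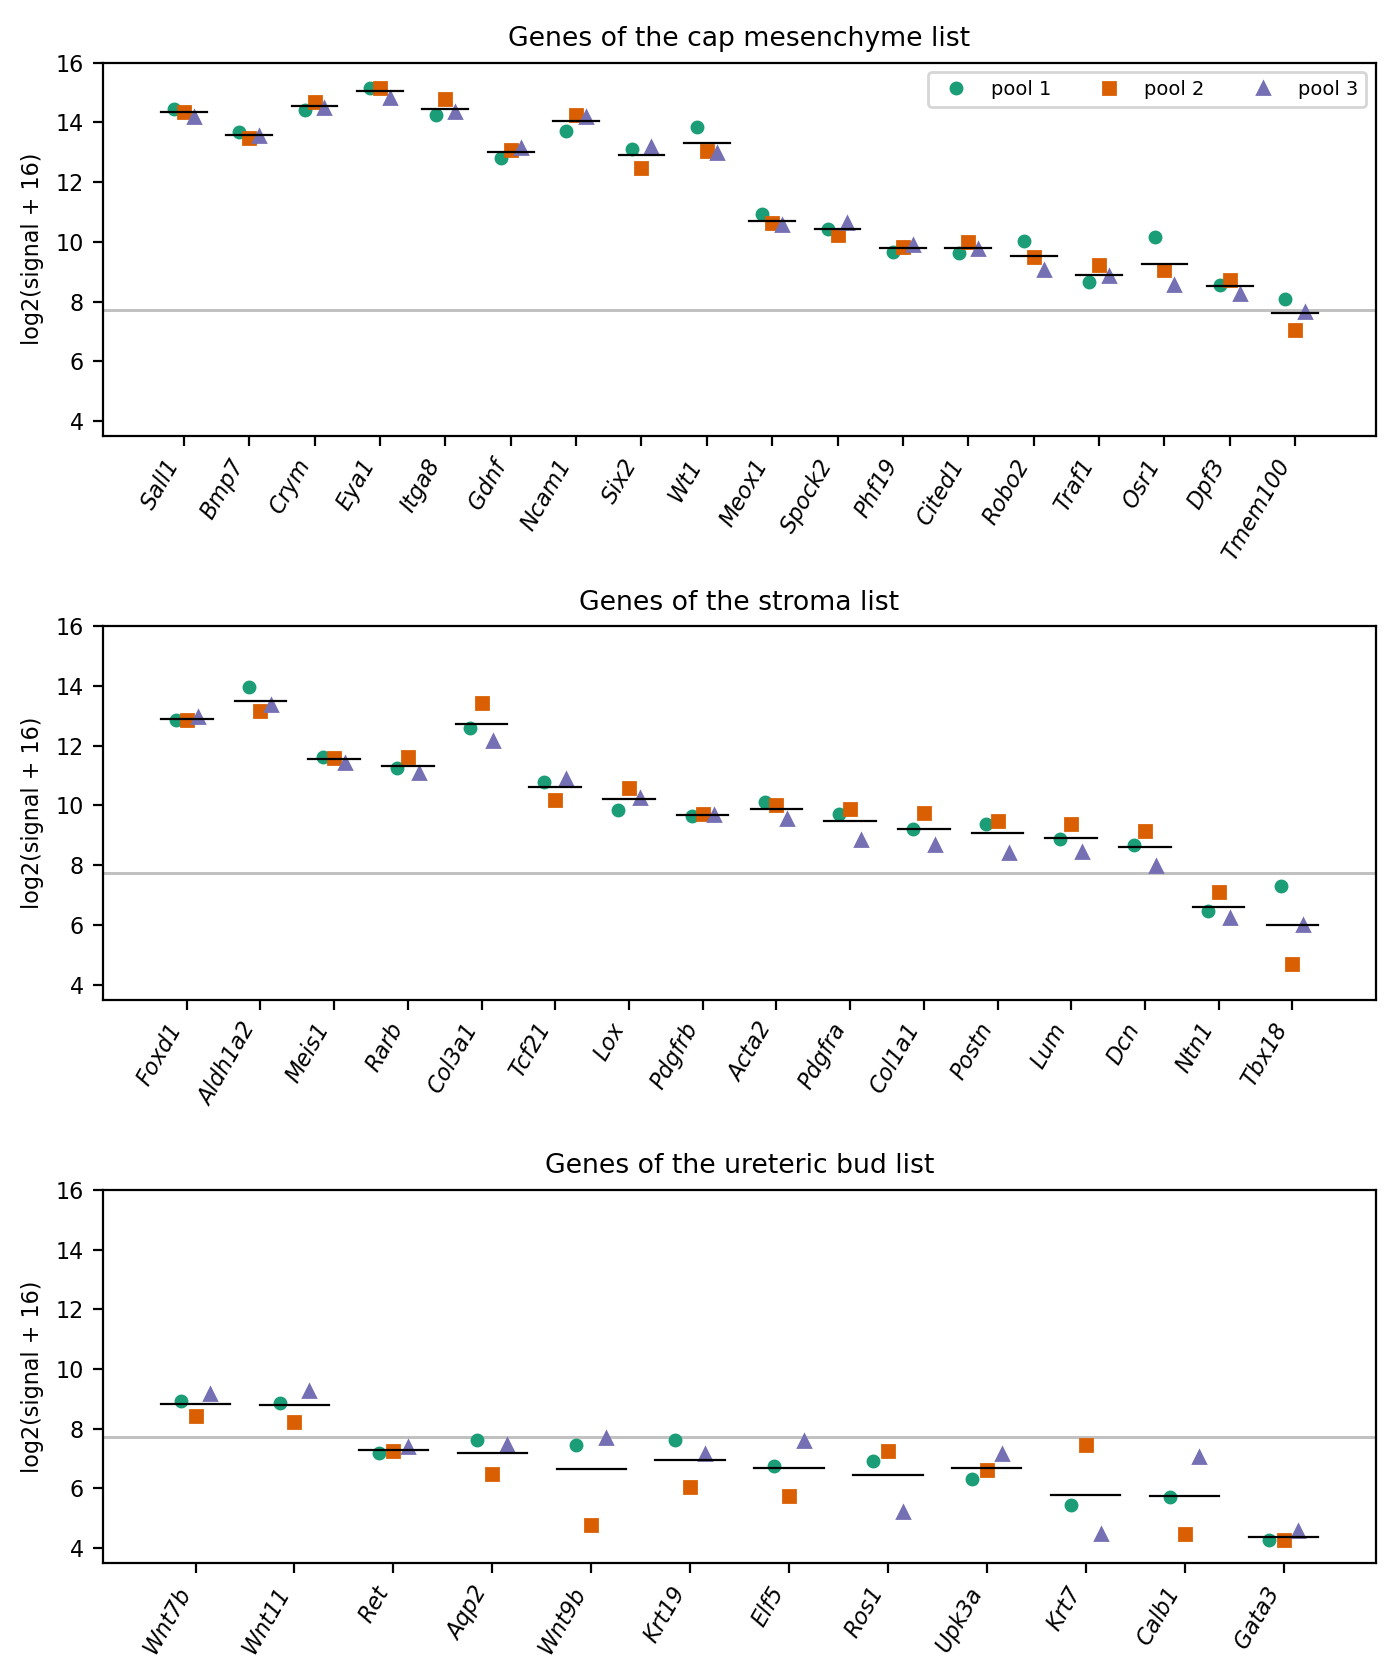
Log2(signal + 16) of each measured gene of the cap mesenchyme, stroma and ureteric bud lists, with 1 point per pool (n = 3), a short black line at the mean and a grey band over the 3 background levels. Of the measured genes 17 of 18, 14 of 16 and 2 of 12 passed the test against background.

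The sine oculis homeobox, Eya and Dach families, which form a transcriptional network in kidney progenitors, were represented by 10 of 11 measured genes (adjusted p = 0.0280, Fisher's exact test with Benjamini-Hochberg adjustment). This list shared 2 measured genes, Six2 and Eya1, with the cap mesenchyme list, and 1, Six3, with the transgene-related list. The cells were sorted by a Six2 transgene, so Six2 is not independent support for the excess of either list that holds it. As a member of the transgene-related list, Six3 may not be independent support for the excess of the sine oculis, Eya and Dach list either. Eya4 had a signal of 22723 ± 3098, Dach1 of 7117 ± 934, Six4 of 2703 ± 773, Dach2 of 2290.4 ± 299.8, Eya3 of 1647 ± 292 and Six5 of 1071 ± 174 (n = 3 each). Eya2 was near the background level (347 ± 29.1), and lost its call without pool 2 and at the 99th percentile of background. Six6, a gene of eye and pituitary development, stayed far below background at 9.497 ± 1.28. The excess of this list was lost without pool 2 (adjusted p = 0.102) and under 3 other settings, within a range of 0.0241 to 0.102 over 10 alternatives. The transgene-related list held Six3, its antisense gene Six3os1 and Cntnap5a, of which 1 of 3 was above background (adjusted p = 0.674, Fisher's exact test). Six3, the neighbour of Six2 on its chromosome, was above background on 1 of 3 probe sets, with signals of 3832, 1859.9 and 1071 in pools 1, 2 and 3 (adjusted p = 3.3e-05, limma), while its other probe sets had mean signals of 58.1 and 7.69. Six3os1 (4.69 ± 0.901) and Cntnap5a (67.3 ± 46.9) were not above background.

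Hox genes, which encode position along the body axis, were detected from paralog groups near the front of the clusters through group 11. Of 33 measured Hox genes, 23 were above background, which did not pass the test against other genes (adjusted p = 0.15, Fisher's exact test with Benjamini-Hochberg adjustment). Hoxa9 had a signal of 39446 ± 4267, Hoxd10 of 21430.4 ± 3624, Hoxc8 of 13095 ± 1940.3, Hoxc4 of 9054 ± 1730.4, Hoxa10 of 8427 ± 688, Hoxa5 of 6832 ± 417 and Hoxc10 of 6713 ± 506 (n = 3 each). Hoxa11 and Hoxd11, which kidney development requires, were at 819 ± 223 and 691 ± 37.1, with adjusted p (limma) of 3.8e-05 and 2.6e-05. Hoxb2 (4738 ± 1086), Hoxc5 (4597 ± 846), Hoxb5 (3943 ± 1224), Hoxb6 (3034 ± 399.6), Hoxd9 (2812 ± 494), Hoxb3 (2552 ± 177), Hoxd8 (2289 ± 415), Hoxc9 (1638 ± 456) and Hoxb4 (1332 ± 165) also passed, as did Hoxa3, Hoxb9, Hoxa2, Hoxd3 and Hoxc6 at mean signals between 480.2 and 905. The measured members of groups 12 and 13 (Hoxd12, Hoxa13, Hoxb13, Hoxc13 and Hoxd13) did not pass, with mean signals from 10.2 for Hoxb13 to 201 for Hoxd13. Hoxa4, Hoxa7, Hoxb1, Hoxb7 and Hoxd1 did not pass either, and Hoxa7 read 435, 150.0 and 30.9 in pools 1, 2 and 3. Hoxa2, Hoxd3 and Hoxc6 lost their calls at the 99th percentile of background, and Hoxc6 also without probe sets that can match several transcripts.

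Components of the signalling pathways that maintain nephron progenitors were above background more often than other genes. In the FGF and receptor tyrosine kinase list 16 of 17 measured genes passed (adjusted p = 0.00263), in the BMP and TGF-beta list 21 of 22 (adjusted p = 0.000270) and in the WNT list 16 of 19 (adjusted p = 0.0196, all by Fisher's exact test with Benjamini-Hochberg adjustment). Igf2, a fetal growth factor, had a signal of 29838 ± 3474, Etv5, a transcriptional target of FGF signalling, of 7627 ± 298, and the decoy receptor gene Fgfrl1 of 9649 ± 934 (n = 3 each). The feedback inhibitor gene Spry4 had signals of 543, 265 and 1368 in pools 1, 2 and 3 (adjusted p = 0.0075, limma), and Fgfr4 did not pass (253 ± 144). Among BMP and TGF-beta genes the signal transducers Smad1 (12504 ± 160.0), Smad5 (13316 ± 352) and Smad3 (10159 ± 303) differed little between pools. They were named for their large moderated statistic, which favours a small spread. Bmpr1b was at 596 ± 41.6, and the BMP antagonist Grem1 did not pass (209.8 ± 66.9). The WNT receptor genes Fzd7 (33572 ± 5814), Fzd2 (32008 ± 7184) and Fzd1 (4801 ± 221) were above background, while Fzd10 (99.9 ± 98.8) and Lrp5 (14.7 ± 13.3) were not. In the Notch list 11 of 16 genes passed, which did not pass the test against other genes (adjusted p = 0.381, Fisher's exact test). Rbpj, the DNA-binding effector of Notch, had a signal of 15915 ± 2084, Notch2 of 8588 ± 918 and Hey1 of 5065 ± 114, whereas Dll3 (129 ± 48.8) and Hey2 (73.4 ± 19) did not pass. Spry4 and Bmpr1b lost their calls at the 99th percentile of background.

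Genes of early nephrons and podocytes were partly represented, and few genes of mature tubules were. Of 17 early nephron genes, expressed as progenitors commit and form vesicles, 10 were above background (adjusted p = 0.811, Fisher's exact test with Benjamini-Hochberg adjustment), including Sfrp2 (17663 ± 3062), Ccnd1 (13104 ± 1583) and Jag1 (5201 ± 782), whereas Fgf8 (27.1 ± 29.1) and Osr2 (18.4 ± 14.01) were not. Of 8 podocyte genes, 5 passed (adjusted p = 0.767, Fisher's exact test): the cell cycle inhibitor gene Cdkn1c was at 9544 ± 678, the adaptor gene Cd2ap at 21240.3 ± 7085 and Npnt, which encodes a matrix ligand of integrins, at 1576 ± 295, but the slit diaphragm gene Nphs1 (110.3 ± 8.68) and Clic5 (119 ± 44.6) did not pass. Proximal tubule genes were above background less often than other genes, with 1 of 12 (adjusted p = 0.00517, Fisher's exact test). That member was Dab2, an endocytic adaptor gene also active outside the tubule (1700.1 ± 72.1, n = 3), while the transporter genes Slc5a2 (173 ± 5.32) and Slc22a6 (52.1 ± 48.02), the endocytic receptor gene Lrp2 (238 ± 116) and the gluconeogenic Fbp1 (44.96 ± 36.9) did not pass. Loop and distal tubule genes passed in 2 of 9 cases (adjusted p = 0.123, Fisher's exact test), namely Trpm6 (802 ± 130.5) and Umod (387 ± 42.9), with Ptger3 (216 ± 110.4), Kcnj1 (41.4 ± 43.1) and Slc12a3 (20.2 ± 4.77) not above background. Umod lay under the background level at its 99th percentile.

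**Figure D2:**
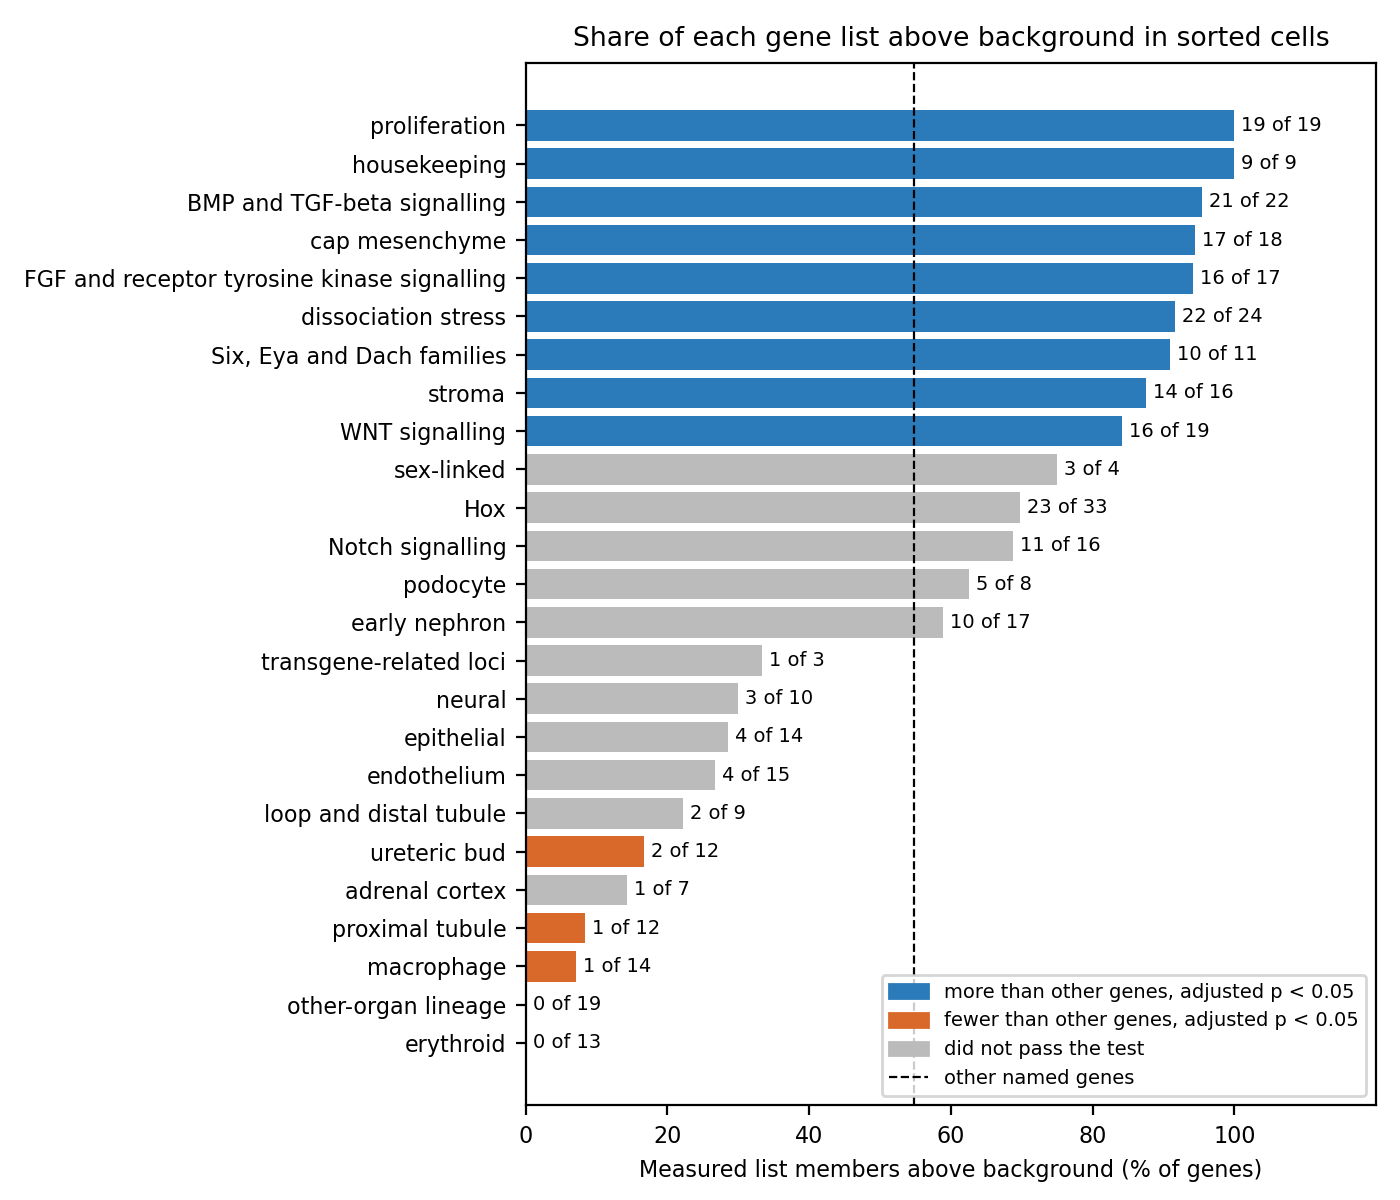
Percentage of the measured genes of each of the 25 lists that were above background in the 3 pools, with the counts beside the bars. Blue and orange bars mark lists above background more or less often than other named genes (adjusted p under 0.05, Fisher's exact test), grey bars mark the other lists, and the dashed line marks the share among other named genes; 9 lists lay above it and 5 below it by this test, 2 of the 5 without a bar because their count is 0.

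Epithelial and ureteric genes, which mark the neighbouring collecting system, were mostly not above background. Of 12 ureteric bud genes 2 passed (adjusted p = 0.0196, Fisher's exact test with Benjamini-Hochberg adjustment): Wnt7b (449 ± 115) and Wnt11 (445 ± 159, n = 3 each). The receptor gene Ret (139 ± 9.75), Calb1 (52.7 ± 56.4) and Gata3 (4.66 ± 2.59) did not pass. The deficit was not kept when probe sets that can match several transcripts were left out (adjusted p = 0.0988, range 0.00274 to 0.0988 over 10 alternatives), and neither Wnt7b nor Wnt11 exceeded the 99th percentile of background. Of 14 general epithelial genes 4 were above background (adjusted p = 0.0889, Fisher's exact test), with Epcam at 1445 ± 202, Crb3 at 452 ± 5.33 and Krt8 at 351 ± 86.7, and with Cdh1 (55.6 ± 23.9) and Esrp1 (6.23 ± 2.63) not above it. The epithelial deficit passed Fisher's exact test when any single pool was left out (adjusted p = 0.0255 without pool 1, 0.0104 without pool 2 and 0.0114 without pool 3, within 0.00618 to 0.0893 over 10 alternatives). In these settings 3, 2 and 2 members were above background in place of 4. The smaller p-values thus came with calls lost on fewer arrays and do not strengthen the deficit. Krt8 lost its call without pool 2, without pool 3 and at the 99th percentile of background, where Crb3 also lost its call.

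Stromal genes were above background in 14 of 16 cases, more often than other genes (adjusted p = 0.0196, Fisher's exact test with Benjamini-Hochberg adjustment). Foxd1, the transcription factor gene that defines cortical stroma, had a signal of 7565 ± 322 (n = 3), the retinoic acid synthesis gene Aldh1a2 of 11845 ± 3526 and Meis1 of 2986 ± 207, whereas Ntn1 (83.9 ± 32.7) and Tbx18 (65.95 ± 67.4) did not pass. The excess was lost without pool 2 (adjusted p = 0.115), at the 99th percentile of background (adjusted p = 0.525) and without probe sets that can match several transcripts (adjusted p = 0.109), within 0.0173 to 0.525 over 10 alternatives.

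Blood, vessel and nerve genes were largely not above background. None of 13 erythroid genes passed (adjusted p = 0.000270, Fisher's exact test with Benjamini-Hochberg adjustment), with Hba-a2 at 275 ± 106, Epor at 181 ± 52.7, Rhd at 117 ± 13.8, Hba-a1 at 12.2 ± 5.87 and Hbb-y at 5.56 ± 1.504. A probe set shared by 4 adult beta-globin genes, chosen after its values were seen, was nevertheless above background at 396 ± 51.7 (n = 3, adjusted p = 0.0044, limma), and Hba-a2 passed when pool 1 was left out. Of 14 macrophage genes 1 passed (adjusted p = 0.00173, Fisher's exact test), the lysosomal membrane protein gene Laptm5 (462 ± 89.5), which lost its call at the 99th percentile of background and without probe sets that can match several transcripts, while Cd68 (296 ± 144), Csf1r (159 ± 24.98), C1qa (9.82 ± 1.42) and C1qc (4.96 ± 0.712) did not pass. Of 15 endothelial genes 4 passed (adjusted p = 0.0611, Fisher's exact test): among them were Ramp2, which encodes a receptor-modifying protein (6867 ± 1163), Egfl7 (591 ± 45.9) and Eng (424 ± 66.5), and Tek (32.4 ± 26.3) and Tie1 (3.82 ± 1.14) did not pass. The endothelial deficit passed Fisher's exact test without pool 2 (adjusted p = 0.0292), without pool 3 (adjusted p = 0.0173) and at the 99th percentile of background (adjusted p = 0.00432), within 0.00432 to 0.0988 over 10 alternatives. In these settings 3, 3 and 1 members were above background in place of 4, so the smaller p-values came with lost calls. Neural genes passed in 3 of 10 cases (adjusted p = 0.252, Fisher's exact test), namely Elavl4 (3581 ± 221), Nefl (952 ± 355) and Dbh (427 ± 94.4), with Stmn2 (33.3 ± 16.2) and Tubb3 (26.5 ± 27.5) not above background. Egfl7, Eng and Dbh lost their calls at the 99th percentile of background, and Dbh also without probe sets that can match several transcripts.

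Adrenal cortex genes, included because the gland adjoins the kidney, passed in 1 of 7 cases (adjusted p = 0.0804, Fisher's exact test with Benjamini-Hochberg adjustment). That gene was Mc2r (384 ± 98.00), which lost its call without pool 1, without pool 2 and at the 99th percentile of background, while Star (245 ± 44.9), Cyp21a1 (152 ± 26.8), Cyp11a1 (36.3 ± 26.1) and Hsd3b1 (14.1 ± 5.99) did not pass. The adrenal deficit passed the test without pool 1 (adjusted p = 0.0106), without pool 2 (adjusted p = 0.0104) and at the 99th percentile (adjusted p = 0.0288), within 0.0104 to 0.0995 over 10 alternatives. None of 19 lineage genes of other organs was above background (adjusted p = 7.02e-06, Fisher's exact test). The largest moderated statistics in limma were those of the cardiac Nkx2-5 (235 ± 52.9), the muscle gene Myod1 (155 ± 33.3) and Neurod1 (123 ± 45.5). The smallest were those of Nanog (7.56 ± 2.45) and Gcg (6.05 ± 1.52). No member of the erythroid or other-organ lists had an adjusted p under 0.05 in limma, and at an unadjusted p under 0.05 the counts were 0 and 0.

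Cell cycle genes were above background without exception. All 19 measured members of the proliferation list passed (adjusted p = 0.000218, Fisher's exact test with Benjamini-Hochberg adjustment), including Top2a (40576 ± 4939), Mcm5 (20154 ± 2097), Cenpa (15469.8 ± 328), Foxm1 (768 ± 116) and Tyms (612 ± 95.2, n = 3 each). Tyms lost its call at the 99th percentile of background, and Cenpa did so without the probe sets that can match several transcripts. Genes induced by tissue dissociation were above background in 22 of 24 cases (adjusted p = 0.000657, Fisher's exact test), with the immediate-early gene Fos at 35389 ± 6623 and the heat shock genes Hsph1 at 19568 ± 2443 and Dnajb1 at 14145 ± 2344, and with Atf3 (276 ± 179) and Junb (143 ± 37.6) not above it. All 9 measured housekeeping genes passed (adjusted p = 0.0130, Fisher's exact test), among them Pgk1 (51037 ± 7838), Hprt (12762 ± 1589.9), Tfrc (16447 ± 1472), Actb (38220.3 ± 12572) and Eef1a1 (90591 ± 42284). For housekeeping genes the excess was not kept without the probe sets that can match several transcripts (adjusted p = 0.104, range 0.00356 to 0.104 over 10 alternatives).

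Stromal and dissociation genes differed between the pools by more than the 95th percentile of random gene lists. The percentiles were not adjusted for the number of lists compared, so a list may exceed the 95th by chance. The median deviation of the 14 stromal genes from their 3-pool mean was 0.03 in pool 1, 0.33 in pool 2 and -0.29 in pool 3 on the log2 scale, a range of 0.62 that lay at the 99.99th percentile of 10000 random lists matched on size and signal. Pool 2 was highest for 9 of these 14 genes and pool 3 lowest for 9. Col3a1, a fibrillar collagen gene chosen after its values were seen, had log2 values of 12.58, 13.42 and 12.14 in pools 1, 2 and 3, whereas Foxd1 had 12.85, 12.85 and 12.96. For the 22 dissociation genes the medians were -0.11, -0.10 and 0.18, a range of 0.29 at the 98.56th percentile, and pool 3 was highest for 12 of them. The dissociation list did not move as one, since pool 3 was lowest for 4 of its genes. Among these were the heat shock genes Hspa1b (11489, 7087 and 3644 in pools 1, 2 and 3) and Hspa1a (3245, 2829 and 1602). Both were chosen after their values were seen. Without pool 3 these ranges came to 0.13 for stroma and 0.01 for dissociation genes, at the 66.43rd and 4.3rd percentiles, and without pool 2 the stromal range was 0.32, at the 91.42nd percentile. Cap mesenchyme genes had a range of 0.11 (36.37th percentile), which came to 0.17 (89.82nd percentile) without pool 1, 0.07 (45.29th) without pool 2 and 0.01 (3.87th) without pool 3. Proliferation genes had a range of 0.07 (10.64th percentile). In the 13 other lists with at least 3 genes above background the range lay below the 95th percentile of random lists with all 3 pools. Of these, housekeeping genes exceeded it without pool 1 (99.43rd percentile) and sine oculis homeobox, Eya and Dach genes without pool 3 (98.82nd).

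**Figure D3:**
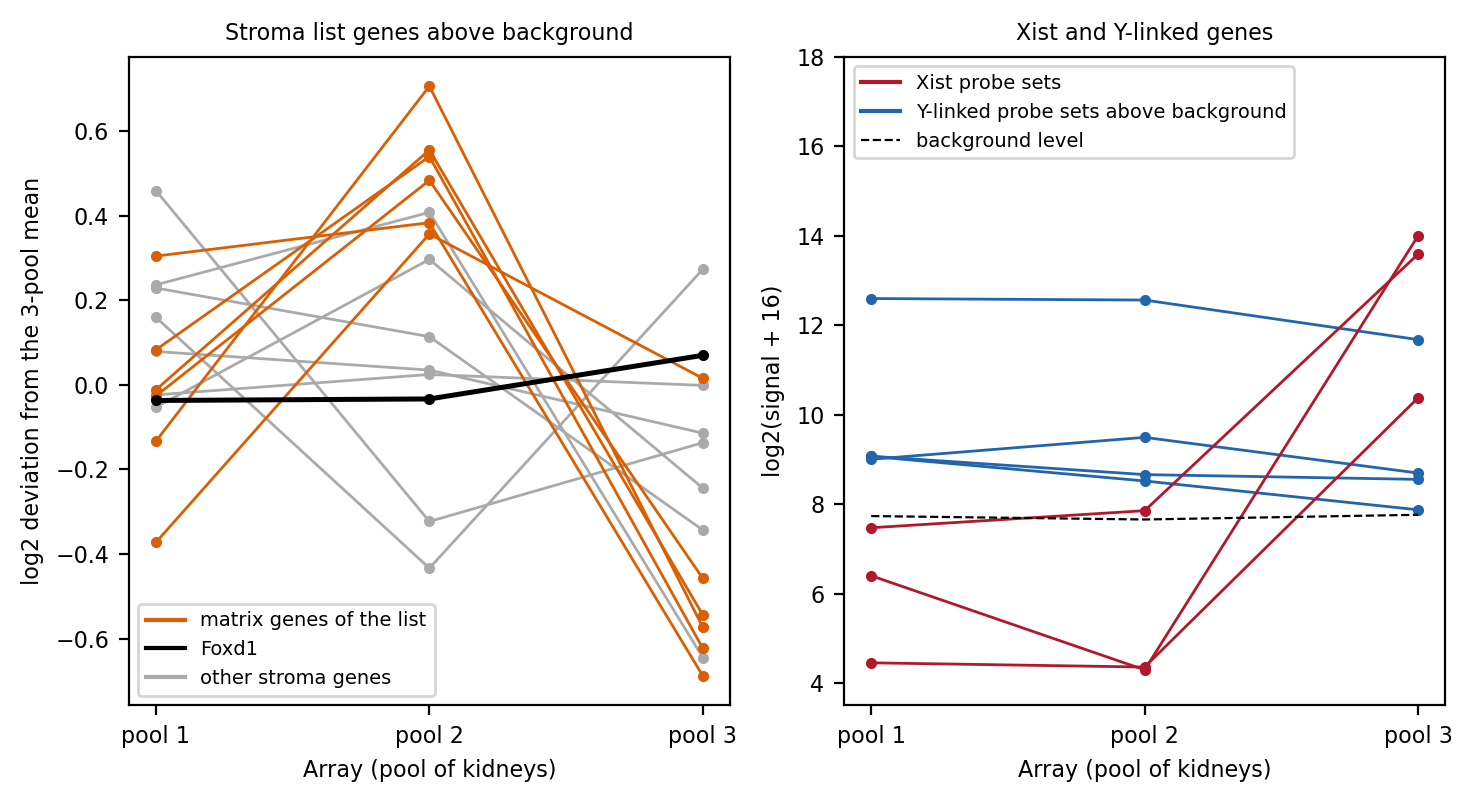
Left, log2 deviation of each stromal gene above background from its mean over the 3 pools, with the matrix genes Col1a1, Col3a1, Dcn, Lum, Postn and Lox, grouped after their values were seen, in orange and Foxd1 in black; right, log2(signal + 16) of the Xist probe sets in red and of the Y-linked probe sets above background in blue, with the background level dashed. Lines join the values of a gene or probe set over the pools, which have no order; Xist signals in pool 3 reach 16338, and no more than 215 in pools 1 and 2.

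Sex-linked genes separated pool 3 from the other pools. Xist, the RNA that coats the inactive X chromosome of female cells, gave signals of 161, 215 and 12287 in pools 1, 2 and 3 on the probe set with the highest mean log2 signal, 68.4, 3.63 and 16338 on another and 5.90, 4.51 and 1312 on the third. With pools 1 and 2 near or below background, Xist did not pass the test over all pools (adjusted p = 0.13, limma) and passed when pool 1 was left out. The Y-linked Eif2s3y had signals of 6168, 6025 and 3256, Kdm5d of 497, 704 and 398 and Uty of 522, 388 and 359 in pools 1, 2 and 3, and all 3 genes were above background, with adjusted p (limma) of 3.4e-07, 0.00098 and 0.0029. In pool 3 Eif2s3y was at 53.4% of its mean in pools 1 and 2. The list as a whole had 3 of 4 genes above background (adjusted p = 0.687, Fisher's exact test). Kdm5d and Uty lost their calls at the 99th percentile of background.

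Probe sets that varied between pools were most often highest in pool 1 and lowest in pool 3. Of 18699 probe sets above background, 2360 (12.6%) had a range of at least 2-fold over the 3 pools, of which 1132 were highest in pool 1 and lowest in pool 3, and 404 showed the opposite order. By pools 1 and 3 alone, 1253 probe sets were at least 2-fold higher in pool 1 and 481 at least 2-fold higher in pool 3. After quantile normalization these 2 counts were 1100 and 662. Leaving out any pool lowered the count of probe sets with a 2-fold range, to 785 without pool 1, 1315 without pool 2 and 1016 without pool 3. Among representative probe sets, 679 of 9891 genes had such a range. The widest was that of the peptide transporter gene Slc15a2, with signals of 2331, 2574 and 121 in pools 1, 2 and 3 on the 1 of its 3 probe sets above background, followed by Alkbh8 (2447, 915 and 287) and the kinetochore gene Knl1 (1615, 639 and 205). Gdap10, Gatad2b, Pygo1, A930013F10Rik and Srrm2 were also highest in pool 1 and lowest in pool 3, with log2 ranges from 2.41 for Srrm2 to 2.74 for Gdap10. The immediate-early gene Egr3 had the opposite order (314, 802 and 2232), and Pafah2 read 594, 228 and 1466. These 10 genes were selected for their range, which 3 arrays estimate poorly.

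Control probe sets of 4 messenger RNAs had higher 3' than 5' signals in every pool after the 2 rounds of amplification, while those of 18S ribosomal RNA were nearly equal in pool 1. For Gapdh the log2 ratio of 3' to 5' signal was 4.36 in pool 1, 5.05 in pool 2 and 4.08 in pool 3, and for Actb it was 1.82, 3.28 and 3.18. The ratio was lowest in pool 1 for Actb, for the transferrin receptor (1.84, 3.15 and 2.57), for pyruvate carboxylase (1.66, 2.09 and 2.65) and for 18S ribosomal RNA (0.03, 0.77 and 1.30), but not for Gapdh.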

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

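The mean over a gene's probe sets and the whole Wnt and Sox families (described with the added lists) were chosen only after the results were seen, and the other alternatives were planned. Quantile normalization changed the call of no named gene and of no list. It changed the number of probe sets above background from 18699 to 18652 and of genes from 9892 to 9882. The cause of the changes that follow was not tested except where named. Leaving out pools 1, 2 and 3 ended the calls of 1, 4 and 1 of the named genes, and 2 others (Hba-a2 and Xist) passed without pool 1. No paired analysis was possible because there is a single group. The number of probe sets above background ranged from 13495 to 19033 over 9 alternatives, and 14485 of the 18699 stayed above at the 99th percentile of background, where the line lay at signals of 379 to 486. At that percentile 22 of the 103 named genes above background lost their calls. Of these, Dbh (-0.0763), Dpf3 (-0.34), Eng (-0.0768), Eya2 (-0.35), Krt8 (-0.35), Mc2r (-0.23), Umod (-0.20), Uty (-0.0866), Wnt11 (-0.0609) and Wnt7b (-0.0178) had mean log2 signals under the line, so signal over background limits these calls. The stroma list was no longer in excess there (adjusted p = 0.525, Fisher's exact test), while the deficits of the endothelium (0.00432), adrenal cortex (0.0288) and epithelial lists (0.00618) passed, and 8 lists in place of 5 had a deficit. Without probe sets that can match several transcripts, the ureteric bud (adjusted p = 0.0988), stroma (0.109) and housekeeping lists (0.104) no longer passed, and Cenpa (-0.22) and Dbh (-0.55) lay under the line. The sine oculis, Eya and Dach list missed the threshold in Fisher's exact test without the intensity trend, with olfactory and vomeronasal background alone and with a pseudocount of 1 (adjusted p = 0.0512 in each case), always with the same direction. Leaving out each pool in turn gave adjusted p (Fisher's exact test) of 0.0241 to 0.102 for sine oculis, Eya and Dach genes, 0.0173 to 0.115 for stroma, 0.0104 to 0.0789 for adrenal cortex, 0.0173 to 0.0566 for endothelium and 0.0104 to 0.0255 for epithelial genes, and 7 to 8 lists with a deficit. The 2 lists that differed between pools (stroma and dissociation) became 1 to 3 lists when a pool was left out, and not the same ones: housekeeping joined them without pool 1 (99.43rd percentile), dissociation alone remained without pool 2, and sine oculis, Eya and Dach genes alone passed without pool 3 (98.82nd). There were 4 with all members in place of those above background, where ureteric bud (98.77th) and housekeeping (97.4th) joined, and 4 with the mean over a gene's probe sets, where sine oculis, Eya and Dach (97.42nd) and sex-linked genes (96.04th) joined. The range of a list moved by more than its SD between pools in 5, 5 and 7 lists without pools 1, 2 and 3, in 5 with the mean over probe sets, where cap mesenchyme reached 0.25, in 2 after quantile normalization and in 1 with all members. The epithelial list had too few genes above background for a range without pool 2 or without pool 3. Probe sets with a 2-fold range numbered 785 to 1315 when a pool was left out, by construction from a smaller number of arrays, and 15868 when weak signals were included, whose median SD was 0.54 against 0.26. The added Sox list passed with the whole family (adjusted p = 0.0313 in place of 0.129, Fisher's exact test). All other lists compared with background kept their side of the threshold, and the other counts above background stayed within 1.5 times.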

Other observations

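The 5 gene lists in the next paragraphs were written after the data had been seen, with the values of a few members already known. The tests of the stromal and Xist patterns were also chosen only after the result was seen, whereas those of the difference between pools 1 and 3 were written down before their outcome, except for 1 count named there. The genes named from the added lists, the matrix genes, Pdgfra, Tcf21 and Malat1 were chosen after their values were seen.

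Chromatin repressor genes were almost fully represented in the sorted cells. Of 15 genes, 14 were above background, against 54.7% of other named genes (adjusted p = 0.00692, Fisher's exact test with Benjamini-Hochberg adjustment over 5 lists). The Polycomb genes Ezh2 (23252 mean signal, n = 3), Eed (21655) and Suz12 (37756), the DNA methyltransferase genes Dnmt1 (24516), Dnmt3a (12169.5) and Dnmt3b (5991) and the corepressor gene Trim28 (38262) all passed, and Cbx3 (295) did not. Of 10 fetal and self-renewal genes 7 passed (adjusted p = 0.528, Fisher's exact test), among them Hmga2 (30090.5), Igf2bp3 (9176), Bmi1 (25838) and Mycn (3643), while Lin28a (8.82, 54.7 and 128 in pools 1, 2 and 3), Lin28b (14.6, 5.200 and 21.7) and Dlk1 (197, 166 and 188) did not.

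Few Wnt ligand genes were above background, with 1 of 14 in the list (adjusted p = 0.00243, Fisher's exact test with Benjamini-Hochberg adjustment). That gene was Wnt5b, with a mean signal of 769 ± 128 (n = 3), and Wnt5a (291 ± 77.3) and Wnt6 (249 ± 43.7) did not pass. The list left out Wnt4, Wnt7b, Wnt9b and Wnt11, which belong to other lists, and Wnt9a, and all of these but Wnt9b passed. With every measured Wnt gene, an alternative chosen after the result was seen, 5 of 19 were above background (adjusted p = 0.0313, Fisher's exact test). Of 15 imprinted genes 10 passed (adjusted p = 0.528, Fisher's exact test), including Grb10 (66578 ± 18384), Peg3 (47949 ± 11834), Ndn (48599.9 ± 9088) and Mest (29773 ± 2599.9), whereas Snrpn (16.4 ± 0.878) and Peg10 (43.8 ± 62.4) did not. Of 16 Sox genes 5 passed (adjusted p = 0.129, Fisher's exact test), and 5 of 19 with the 3 Sox genes of other lists (adjusted p = 0.0313, chosen after the result was seen): Sox4 (29375 ± 4112), Sox11 (23927 ± 3353), Sox12 (2132 ± 164), Sox13 (558 ± 269) and Sox9 (379.5 ± 86.7).

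Of the probe sets above background, 1253 were higher in pool 1 than in pool 3 by at least 2-fold, and 481 were higher in pool 3. A difference in the amount of whole transcripts is argued against as the general case, in the 759 genes with another probe set above background. There the other probe sets had a median log2 difference of 0.0727 (95% bootstrap interval 0.0369 to 0.104), against 1.54 for those in the pattern. Selection widens this contrast, since the probe set with the largest difference was taken from each gene and the others were what remained. In 32 of these genes the other probe sets also moved by at least 2-fold. The scaling of the arrays does not account for the whole pattern, since 1100 probe sets met the same criterion after quantile normalization. The excess over the opposite direction was smaller after that normalization, since 662 were then higher in pool 3, a count made after the other outcomes were seen. Quantile normalization makes the distributions of the arrays equal whatever made them differ. The smaller excess thus does not show that scaling gave part of it. Probe sets without a gene name were more common in the pattern (18.4%) than among the other probe sets above background (8.49%), with an odds ratio of 2.42 (95% confidence interval 2.07 to 2.83, Fisher's exact test). Only 230 of the 1253 lacked a name, and the comparison was not matched on signal. The positions of these probe sets were not examined. Whether parts of transcripts outside annotated genes, such as introns or extended 3' ends, carry part of the pattern thus stays open. Whether pool 1 differed in RNA processing, in nuclear RNA or in the amplification stays open, and no biological explanation was tested. The log2 ratio of 3' to 5' control signals given above was lowest in pool 1 for every control but Gapdh. Whether that difference between the pools bears on the pattern was not tested.

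Foxd1, the gene of cortical stroma, was above background in a population sorted by a Six2 transgene, and its level did not follow the matrix genes of the stroma list. The 6 matrix genes Col1a1, Col3a1, Dcn, Lum, Postn and Lox had a median log2 difference of 1.09 between pool 2 and pool 3, while Foxd1 differed by -0.10, with a typical SD of 0.19 at its level. The matrix genes were lower in pool 1 than in pool 2 (median -0.54). They were grouped after all 6 had been seen to be highest in pool 2, which fixes the sign of both medians, and other genes of the list went either way between pools 2 and 3, such as Pdgfra (1.05) and Tcf21 (-0.71). Whether the same contaminating cells brought the matrix and the Foxd1 transcripts, and whether amplification differences of the kind seen between pools 1 and 3 gave the matrix pattern, thus stays open. A constant share of Foxd1-expressing cells without matrix genes, or Foxd1 transcripts within the sorted progenitors, could each also give the values, and neither of these was tested.

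Xist was far above background in pool 3 alone. A faulty probe set is argued against, since all 3 Xist probe sets were higher in pool 3 than in the other pools, by at least 5.73 on the log2 scale. Female cells only in pool 3 are argued against, since the representative probe sets of its 3 Y-linked genes lay at least 0.791 log2 units above background. All 3 Y-linked genes were lower in pool 3 than in both other pools, which is consistent with female and male embryos in pool 3 and male embryos in pools 1 and 2. The log2 difference of pool 3 from the mean of pools 1 and 2 was -0.90 for Eif2s3y, -0.55 for Kdm5d and -0.31 for Uty. Kdm5d (497 and 704) and Uty (522 and 388) also differed between pools 1 and 2. Lower values in pool 3 were not particular to Y-linked genes, since 1253 probe sets were at least 2-fold lower there than in pool 1 and 481 higher. The sex of the embryos is unknown per the labels, and pools of a few kidneys may differ in sex by chance. Whether sex accounts for any other difference between pool 3 and the others was not tested.

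Of the 6 Malat1 probe sets above background, 5 were higher in pool 1 than in pool 3 by at least 2-fold, and the remaining probe set read 20377, 26912 and 23343 in pools 1, 2 and 3.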
